A study of Escherichia coli BW25113 with 2 samples.

How the data were processed

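RNA of 2 Escherichia coli K-12 strains was compared on 2 two-colour Agilent arrays. BW25113 is a K-12 laboratory strain, and pBAD33 is a plasmid vector with an arabinose-inducible promoter. Per the labels, channel 1 (Cy3, green) of each array held BW25113 with the empty vector, and channel 2 (Cy5, red) held BW25113 with the plasmid that expresses FimZ. FimZ is a DNA-binding response regulator encoded beside fimbrial genes. Cultures were grown in LB medium with 0.2% arabinose at 27 °C into the stationary phase, and RNA was taken by hot phenol extraction with DNase treatment. Labelled cDNA was made from 10 µg of RNA with the FairPlay III kit. Both arrays carried the dyes in the same orientation, so a dye effect cannot be separated from the difference between the strains. The labels number the arrays 1 and 2 and do not say whether they came from separate cultures, so p-values measure only the spread between these 2 arrays, which may be technical.

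The scanner tables were made with Agilent Feature Extraction 8.1, per the submitters' processing notes. Per the file headers, the deposited intensities were the median spot signal and the median local background of each channel, with Feature Extraction's background-subtracted signal and its processed signal. The processed signal was background-subtracted and dye-normalized by a method that is not given in the sources used here. The deposited LogRatio column held log10 of red over green, that is, of the FimZ-expressing over the vector strain. The deposited p-value of each log ratio comes from Feature Extraction's error model for 1 spot and was used only to count spots. The deposited value table of the series equalled that log10 ratio on each array within 0.00498, which settled its scale and direction and showed no added centring. Its column medians were 0 for replicate 1 and 0.0057 for replicate 2.

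Each array held 10751 probes, of which 60 were controls. Probes were named through the locus tag in the systematic name, because the symbol column of replicate 1 did not belong to its rows: it equalled the current symbol for 0% of the probes, against 89% on replicate 2. The gene table of assembly ASM584v2 (strain MG1655) supplied the names and the order of genes. Of 4234 probes with a K-12 locus tag, 4073 matched directly, 117 through a synonym that named 1 gene, and 44 did not match and were left out. The 4190 named probes covered 4107 genes. The 6457 probes named for other genomes or in other ways entered no test, but they took part in the background correction and the loess fit.

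The background was corrected with normexp (offset 50) on the median signals and median backgrounds, where the plan had named mean signals. Loess was then fitted within each array with control spots at weight 0. Spots marked as outliers by Feature Extraction were left out after that fit (77 on replicate 1, 228 on replicate 2), and no spot was saturated. Log2 ratios of different probes of a gene were averaged. Of 73 genes with several probes, 9 had probes more than 1 log2 unit apart. A gene was tested when at least 1 probe was well above background in at least 1 channel on both arrays, which left 3470 genes. The offset pulls the ratios of dim probes towards 0.

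Ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, two-sided), with Benjamini-Hochberg adjustment over the 3470 genes and a threshold of 0.05. With 2 arrays the fit has 1 residual degree of freedom per gene, and the prior estimated from all genes added 4.08. Where a gene was not well above background in one channel on both arrays (43 genes), its fold is a bound, written "at least": the bright channel's mean over the higher of the dim channel's own signal and the lowest signal among probes well above background, after loess and Aquantile normalization. Such bounds are open to dye bias.

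Before the data were examined, 39 gene lists were fixed from general knowledge of E. coli, with the tests, the alternatives and the rule for named genes. The 38 lists with at least 3 tested members were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists). The named genes are fimZ, the 12 highest and the 12 lowest mean ratios among genes past the threshold with the same sign on both arrays, and the 3 tested members with the largest absolute ratio of each shifted list and of the sfm, type 1, curli and both flagellar lists. Operon neighbours of these may be named with their values, and the text says where another gene was chosen after its values were seen.

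The steps were tested on arrays simulated from the brightness, background and spread of this comparison, with 3557 genes in the fit. A true log2 change of 1 was recovered in 11 of 66 genes (16.7%), a change of 2 in 40 of 67 (59.7%) and a change of 3 in 51 of 67 (76.1%). Their median estimates were 0.57, 0.99 and 1.97, and 8.1% of the calls (9 genes) were false. The list test called the list of changed genes, and it called 0 of 100 random lists. Noise was drawn for each probe separately, so the simulated genes had no correlated noise. The simulation therefore cannot tell whether camera's preset correlation is large enough for lists of genes that vary together.

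Alternatives were Feature Extraction's processed signals, no background subtraction, median centring, Feature Extraction's log ratio, the deposited value table, scaling between the arrays, no filter on dim probes, a filter on both channels, the brightest probe per gene, a fit of the 4 channels without the array as a block, a trended and robust prior, an estimated correlation, fry, and each array alone. Outlier spots kept, an offset of 10, and processed signals with the filter on both channels were added after seeing the data.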

Results

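The data were 2 two-colour arrays that set stationary-phase E. coli BW25113 expressing the fimbrial regulator FimZ from a plasmid against the same strain with the empty vector. The comparison asks which genes FimZ changes in the stationary phase. Both arrays were dim. Over 10691 probes per array, the median signal in the FimZ channel was 45 on replicate 1 and 78 on replicate 2, over a median background of 31 on both. The vector channel had median signals of 78 and 110 over backgrounds of 23 and 25. Of the K-12 probes, 74.6% and 97.3% were well above background in the FimZ channel and 84.3% and 84.2% in the vector channel. The log2 ratios of the arrays had a Pearson correlation of 0.86 across genes, which are not independent replicates, and a standard deviation of 0.70 on replicate 1 and 1.07 on replicate 2. The number of arrays limits the precision of every value.

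The transcript of fimZ (b0535) was 38.3-fold higher in the FimZ-expressing strain, with a log2 ratio of 5.26 ± 0.44 (SD, n = 2; 4.95 and 5.57 on the arrays; limma adjusted p = 0.0061). It was the highest ratio among the genes past the threshold, and the probe does not tell the plasmid copy from the chromosomal gene. The sfm operon beside it, which encodes the subunit, chaperone and usher of a fimbria, was higher too. The subunit gene sfmA (b0530) had a log2 ratio of 4.26 ± 0.79, a 19.2-fold higher level (limma adjusted p = 0.0065), and the chaperone gene sfmC was at least 3.77-fold higher (adjusted p = 0.024), since its vector channel was not well above background. Of the 3 sfm genes tested, 2 rose over all genes tested and 2 when adjusted over the list alone. The third, sfmH, had log2 ratios of 0.09 and 0.58 on the arrays, with a vector channel not well above background, and was not distinguished from no change (adjusted p = 0.37). It passed with processed signals (limma adjusted p = 3.822e-06), with Feature Extraction's log ratio (2.84e-08) and with the deposited value table (2.195e-08). The usher gene sfmD was left out because its spot was marked as an outlier on replicate 2, and sfmF was well above background only in the FimZ channel of replicate 2 and was not tested. The list was shifted upward with a median log2 ratio of 2.05, or 1.92 with these genes at their bounds (camera adjusted p = 0.0044). That call was lost with an estimated correlation (adjusted p = 0.81), which rests on 1 residual degree of freedom. In Feature Extraction's processed signals the folds were larger, 67.7 for fimZ and 112 for sfmA. Those signals have no offset and differ also in background subtraction and dye normalization. No processed fold is given for sfmC and sfmH, whose vector channel was not well above background. The call of sfmC was lost without the filter on dim probes and with a trended and robust prior.

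**Figure D1:**
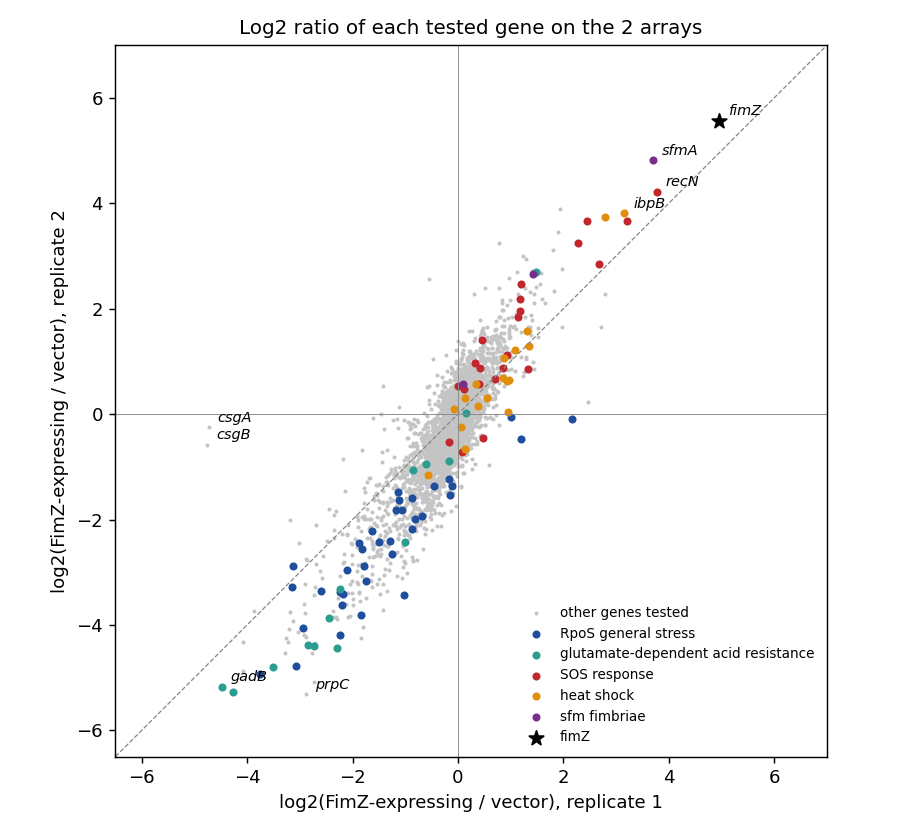
Log2 ratio of FimZ-expressing over vector strain of each of the 3470 tested genes on replicate 1 (horizontal) and replicate 2 (vertical), with the dashed line marking equal ratios and 5 gene lists and fimZ in colour. RpoS and acid resistance genes lie mostly in the lower left, SOS, heat shock and sfm genes mostly in the upper right, and csgA and csgB lie near -4.7 on replicate 1 only.

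Of 3470 genes tested, 116 were higher and 401 lower in the FimZ-expressing strain, and each of them had the same sign on both arrays. Higher genes were 22.4% of the calls. That share depended on the settings: it was 36.8% with processed signals (564 higher, 967 lower), 41.0% with Feature Extraction's log ratio (645 and 928) and 9.2% with median centring (97 and 960). It was 10.6% with a trended and robust prior and 18.3% without the filter on dim probes, neither of which changes a gene's ratio. With an offset of 10, which is added before the loess fit and changes the ratios, it was 28.2%. By size alone, 65 genes were at least 2-fold higher and 291 at least 2-fold lower on both arrays. Replicate 1 alone had 76 and 314 such genes, and replicate 2 alone had 231 and 688. The median log2 ratio of all genes tested was -0.10, and it moved to -0.20 with processed signals and to -0.26 with median centring, so ratios near 0 have to be read relative to it. With a trended and robust prior, 14 higher and 115 lower genes of these kept their call.

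The lowest transcripts belonged to acid resistance. The glutamate decarboxylase gene gadB fell 28.4-fold (log2 ratio -4.83 ± 0.49, n = 2, limma adjusted p = 0.0061), and the glutamate antiporter gene gadC fell 27.4-fold (-4.77 ± 0.71). The periplasmic acid chaperone gene hdeA was 17.9-fold lower (-4.16 ± 0.92), and its operon neighbour hdeB was 12.2-fold lower (-3.61 ± 1.08). The glutaminase gene glsA, which supplies glutamate, had a log2 ratio of -3.90 ± 0.88 and passed. Of 14 tested genes of the glutamate-dependent acid resistance list, 10 fell and 1 rose, and 11 fell and 1 rose when adjusted over the list alone. The median log2 ratio was -2.97. The gene that rose was yhiD (2.09 ± 0.87, against 1.45 with processed signals), named here after its values were seen. The list was shifted downward (camera adjusted p = 0.000166), though not with an estimated correlation (adjusted p = 0.81).

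Genes of the RpoS general stress response, which E. coli uses on entry into the stationary phase, were lower as a group. Of 36 tested, 26 fell and none rose, and 30 fell when adjusted over the list alone. Their median log2 ratio was -1.95 (-1.39 on replicate 1 and -2.44 on replicate 2). The osmotically inducible lipoprotein gene osmB fell 20.3-fold (-4.34 ± 0.84), the transaldolase gene talA 15.2-fold (-3.93 ± 1.20), and the cyclopropane fatty acid synthase gene cfa 11.3-fold (-3.49 ± 0.79), or 20.8-fold with processed signals. Camera gave the list an adjusted p of 1.626e-10 and, with an estimated correlation, adjusted p = 0.81. All 3 tested ribosome hibernation genes fell, over all genes and adjusted over the list alone: rmf by 3.80 ± 0.10, raiA by 2.82 ± 0.10 and hpf by 2.07 ± 0.77 on the log2 scale. With processed signals the falls of rmf and hpf were smaller, at 3.14 and 1.26. Their list had camera adjusted p = 0.0027 (adjusted p = 0.81 with an estimated correlation), and the call of hpf was lost with a trended and robust prior. Among other genes at the low end, ybgS fell 22.3-fold, the outer membrane protein gene ompX 18.4-fold and the methylglyoxal reductase gene dkgA 13.7-fold. The propionate catabolism genes prpC (-4.10 ± 1.72) and prpD (-3.90 ± 1.66) fell, as did their operon neighbours prpB (-3.52 ± 1.15) and prpE (-3.04 ± 1.71).

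Genes of the SOS response to DNA damage were higher. Of 22 tested, 12 rose and none fell, and 14 rose when adjusted over the list alone. The repair gene recN rose 16.0-fold (log2 ratios of 3.77 and 4.22 on the arrays, limma adjusted p = 0.0061), the recombinase gene recA 10.9-fold (3.44 ± 0.32) and the RecA modulator gene dinI 8.37-fold (3.06 ± 0.86). The DNA damage-inducible gene yebG rose 6.81-fold, and the cell division inhibitor gene sulA also rose 6.81-fold. With processed signals the folds were 33.0 for recN, 17.7 for recA, 31.6 for dinI and 11.1 for yebG, but 5.08 for sulA. The median log2 ratio of the list was 0.98 (0.90 and 1.05 on the arrays), with camera adjusted p = 1.918e-10. With an estimated correlation the adjusted p = 0.81.

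Heat shock genes were higher as a list. Of 18 tested, 6 rose and none fell, and 9 rose and 1 fell when adjusted over the list alone. The small chaperone genes ibpB and ibpA rose 11.2-fold (3.49 ± 0.46) and 9.65-fold (3.27 ± 0.68), and the protease subunit gene hslU rose 2.73-fold (1.45 ± 0.19). The call of hslU was lost with a trended and robust prior (adjusted p = 0.077). The major chaperone gene dnaK, named after its values were seen, had a log2 ratio of -0.86 ± 0.41 and did not pass over all genes. It was the 1 gene that fell when adjusted over the list alone, and it passed as lower with processed signals (-0.94, limma adjusted p = 0.035). The list's median log2 ratio was 0.63 (0.86 on replicate 1 and 0.59 on replicate 2), with camera adjusted p = 1.023e-05 and, with an estimated correlation, adjusted p = 0.81. The genes ibpA, ibpB and hslU lie 2.5%, 2.5% and 8.3% of the way from the replication origin to the opposite point of the chromosome. Such distances, here and below, are counted in genes along the MG1655 order, not in base pairs. The median log2 ratio of genes in the 10% of the way nearest to the origin was 0.20.

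In the phage shock list, which answers damage to the inner membrane, 3 of 6 tested genes rose and none fell, and 5 rose when adjusted over the list alone. The gene pspA was not among the genes tested. The genes pspD, pspB and pspC of one operon had log2 ratios of 1.48 ± 0.15, 1.29 ± 0.47 and 1.14 ± 0.06, and pspD was at 2.21 with processed signals. Their list had a median of 1.09 and camera adjusted p = 0.0016 (adjusted p = 0.81 with an estimated correlation). The call of pspC was lost with processed signals (0.77, adjusted p = 0.075), those of pspB and pspC without the replicate block, that of pspB without the filter on dim probes, and all 3 with a trended and robust prior. In the sigma E envelope stress list, 6 of 13 genes fell and 1 rose, the same numbers as when adjusted over the list alone. The anti-sigma factor gene rseA (-2.84 ± 0.38), the sigma factor gene rpoE (-2.41 ± 1.05) and the periplasmic protease gene degP (-2.03 ± 0.26) fell, though the call of degP was lost with a trended and robust prior (adjusted p = 0.054). With processed signals rpoE was at -3.29 and degP at -2.80. The gene that rose was bamE (1.78 ± 0.47), the neighbour of recN, named after its values were seen. The sigma E list had a median of -0.72 (-0.65 on replicate 1 and -1.14 on replicate 2), at percentile 11.9 of 10000 random lists matched on brightness, which leaves its shift doubtful. Its camera adjusted p was 0.012, which became 0.071 with processed signals and adjusted p = 0.81 with an estimated correlation.

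Genes of cysteine synthesis and sulfate assimilation were lower. Of 19 tested in the cysteine and sulfur list, 10 fell and none rose, and 12 fell and 1 rose when adjusted over the list alone. The sulfate adenylyltransferase genes cysD and cysN fell 11.8-fold (-3.56 ± 0.96) and 8.51-fold (-3.09 ± 1.08), and the sulfite reductase gene cysI fell 7.37-fold (-2.88 ± 0.86). Their operon neighbours cysC (-2.87 ± 1.04) and cysJ (-2.80 ± 1.16) fell too. With processed signals cysD was 32.4-fold lower. The list's median was -1.76, with camera adjusted p = 0.000437 and, with an estimated correlation, adjusted p = 0.81. In the oxidative stress list, 7 of 18 genes fell and none rose, and 11 fell when adjusted over the list alone. They included the iron-sulfur cluster assembly genes sufD (-2.61 ± 1.23) and sufC (-2.33 ± 1.27) and the manganese superoxide dismutase gene sodA (-2.40 ± 0.42). The calls of sufD and sufC were lost without the filter on dim probes (adjusted p = 0.053 and 0.066), while with processed signals sufD was 19.6-fold lower, against 6.12-fold here, and sufC 11.7-fold, against 5.02-fold. The median was -1.29 (-0.71 on replicate 1 and -1.79 on replicate 2), with camera adjusted p = 0.0027 and adjusted p = 0.81 with an estimated correlation. Of 6 galactitol uptake and catabolism genes, 4 fell and none rose, and 6 fell when adjusted over the list alone. The lowest were gatY (-1.91 ± 0.33), gatZ (-1.74 ± 0.17) and gatA (-1.23 ± 0.23), and gatZ was 1.81-fold lower with processed signals against 3.35-fold here. The galactitol list had a median of -1.15, at percentile 11.5 of 10000 random lists matched on brightness, and camera adjusted p = 0.0027 (adjusted p = 0.81 with an estimated correlation and 0.051 with an offset of 10, chosen after seeing the data). All 3 gene calls were lost with a trended and robust prior, and those of gatZ and gatA also without the replicate block.

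Branched-chain amino acid synthesis was shifted upward by a few members. Of 14 genes tested, 3 rose and none fell, and 4 rose when adjusted over the list alone. The gene ilvG (2.12 ± 1.26) and the acetolactate synthase gene ilvB (1.86 ± 0.60) passed. The gene ilvM (1.59 ± 1.15) did not, and ilvN, in the operon of ilvB, passed at 1.39 ± 0.61. The calls of ilvG and ilvB were lost with a trended and robust prior (adjusted p = 0.057 and 0.069), and that of ilvG without the filter on dim probes (0.075). The gene ilvM passed with processed signals (2.56, adjusted p = 1.763e-06), without background subtraction (0.023), with median centring (0.020), scaling between the arrays (0.000900), the filter on both channels (0.032) and the brightest probe (0.046). The median was 0.36 (0.11 on replicate 1 and 0.61 on replicate 2) and fell to 0.005 with median centring. Camera gave adjusted p = 0.012, against 0.056 with processed signals and adjusted p = 0.81 with an estimated correlation. The genes ilvG and ilvB lie 1.1% and 3.3% of the way from the replication origin. Of 52 ribosomal protein genes, 1 rose and none fell, and none passed when adjusted over the list alone. The gene that rose was rpsQ (1.07 ± 0.39), whose call was lost with processed signals and in several other settings. With processed signals 13 ribosomal protein genes rose and 2 fell. The log2 ratio of rpmG was 1.15 ± 0.63 and that of rpmI -1.01 ± 0.47, both short of the threshold with the main settings. Both passed in most others, such as processed signals (adjusted p = 0.017 and 0.0019), no background subtraction (0.032 and 0.036), scaling between the arrays (0.0013 and 0.010) and no replicate block (0.048 for each). The ribosomal median was 0.18 (0.03 on replicate 1 and 0.41 on replicate 2), with camera adjusted p = 0.0027 (adjusted p = 0.81 with an estimated correlation). Among other genes at the high end, rspA, annotated as a starvation-sensing protein, rose 7.54-fold (2.92 ± 1.39), against 3.10-fold with processed signals, and lost its call without the filter on dim probes (adjusted p = 0.053). The tryptophan synthase gene trpA rose 6.42-fold (2.68 ± 1.11) and lost its call without the replicate block (adjusted p = 0.068), while its operon neighbours trpB and trpC had log2 ratios of -0.48 and -0.64 and did not pass. The putrescine catabolism gene puuC rose 5.79-fold (2.53 ± 0.37), and its operon neighbours puuE (2.18 ± 0.76) and puuB (1.81 ± 0.24) rose with it.

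**Figure D2:**
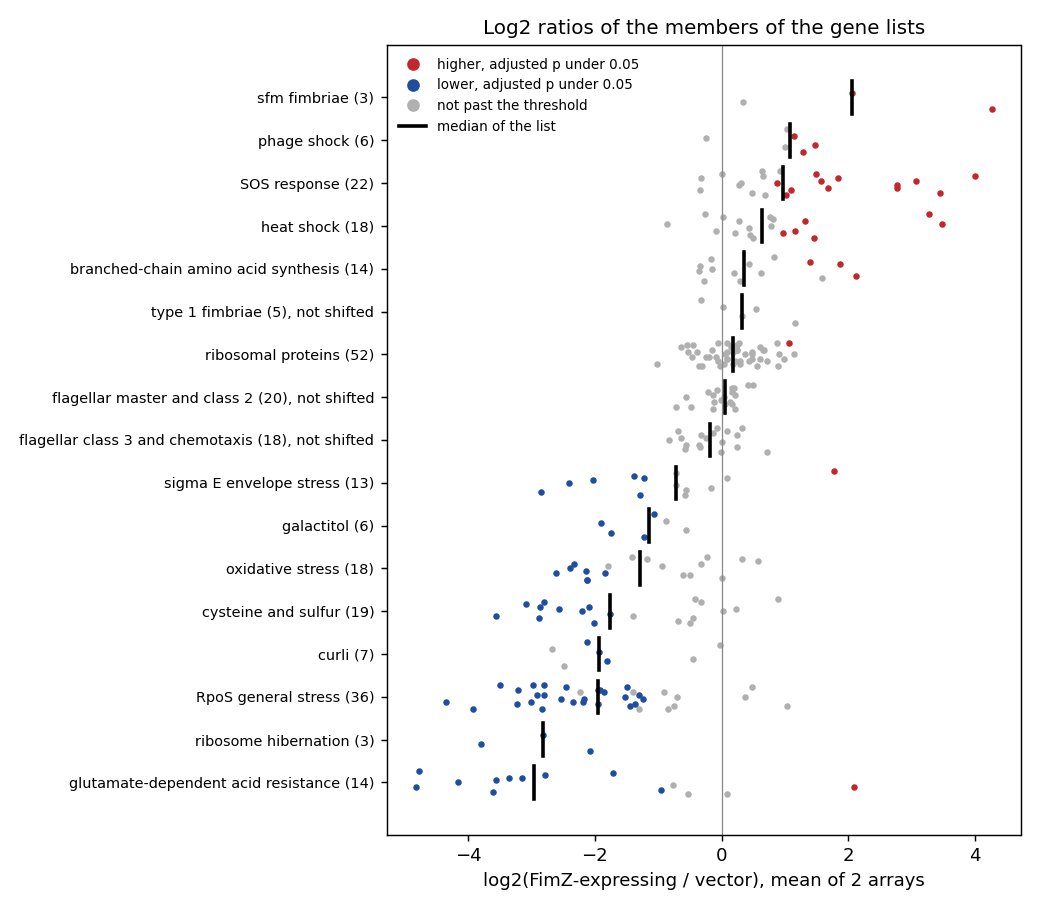
Mean log2 ratio of FimZ-expressing over vector strain (2 arrays) of each tested member of the 14 shifted lists and of the type 1 and flagellar lists, with the number of tested members in brackets. Red and blue points passed the threshold of 0.05, grey points did not, and black bars mark medians, which run from -2.97 for acid resistance to 2.05 for the sfm genes.

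Curli genes, which encode the amyloid fibres of biofilms, were lower, but the arrays disagreed. Of 7 tested, 3 fell and none rose, both over all genes and adjusted over the list alone. The regulator gene csgD fell (-2.12 ± 0.46, limma adjusted p = 0.013, but 0.0501 with a trended and robust prior), as did its operon neighbours csgE (-1.93 ± 0.03) and csgF (-1.80 ± 0.49). Their operon neighbour csgG did not pass, with log2 ratios of -0.16 and 0.12 on the arrays (limma adjusted p = 0.96). The fibre genes csgA and csgB had log2 ratios of -4.73 and -4.75 on replicate 1 and of -0.25 and -0.58 on replicate 2, and did not pass. With processed signals they passed (adjusted p = 0.0036 for csgA and 0.00041 for csgB), and 6 of the 7 genes fell, csgD to -2.94. Both also passed with scaling between the arrays, an offset of 10 and a trended and robust prior. The prior added 24.47 degrees of freedom with processed signals, against 4.08 in the main fit. With an offset of 10 and, at the median gene, with a trended and robust prior, that number was infinite. A gene's own spread between the arrays can count for little there, so these passes do not show that the arrays agree. The median of the list was -1.93 (-2.15 on replicate 1 and -0.58 on replicate 2). Camera gave adjusted p = 0.017, lost with an estimated correlation (adjusted p = 0.81), with scaling between the arrays and with the filter on both channels.

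With the main settings, type 1 fimbrial and flagellar genes did not pass the test as lists or as single genes. Many flagellar genes were dim, such as flhD, with log2 signals of 5.93 in the FimZ channel and 6.42 in the vector channel. The FimZ channel of motB and cheA was not well above background. Since the offset pulls the ratios of dim genes towards 0, the lack of calls does not show that these genes were unchanged. Of 5 type 1 fimbrial genes tested, none passed over all genes, and 1 rose when adjusted over the list alone. The subunit gene fimA had a log2 ratio of 1.15 ± 0.64 (adjusted p = 0.056), fimI of 0.55 ± 0.02 and fimG of 0.33 ± 0.64. The type 1 median was 0.33 (camera adjusted p = 0.17) and 0.04 with median centring. With processed signals 3 of them rose and 1 fell, and fimA was at 1.93 and passed (adjusted p = 6.265e-05). It also passed without background subtraction (adjusted p = 0.025), with median centring (0.041), scaling between the arrays (0.0013), the filter on both channels (0.033) and the brightest probe (0.042). The genes fimI (1.65) and fimG (1.31) passed with processed signals, and fimI with scaling between the arrays. With processed signals and the filter on both channels, chosen after seeing the data, the type 1 list was shifted upward (median 1.48, camera adjusted p = 0.019). Of 20 flagellar master and class 2 genes, none passed over all genes or adjusted over the list alone, and 3 had the largest ratios: fliZ (-0.72 ± 0.22), flhC (-0.56 ± 0.43) and flgF (0.49 ± 0.49). The class 2 median was 0.05 (camera adjusted p = 0.40) and -0.01 with processed signals, where 2 genes rose and 4 fell. Of these, fliZ (-2.63) and flhC (-1.74) passed there. Of 18 flagellar class 3 and chemotaxis genes, none passed either way. The largest ratios were those of flgN (-0.82 ± 0.35), aer (0.72 ± 0.58) and flgM (-0.69 ± 0.13). The class 3 median was -0.18 (camera adjusted p = 0.75). With processed signals it was -0.79, with 9 genes lower and 2 higher, flgN (-2.60), flgM (-1.62) and aer (2.66) among them, and the list again was not shifted (camera adjusted p = 0.31). Single flagellar calls came up in other settings too. The genes fliZ and flgN passed without background subtraction (adjusted p = 0.042 and 0.028), fliZ, flgN and flgM with median centring (0.030, 0.024 and 0.010), and fliZ, flhC, flgN, aer and flgM with scaling between the arrays, with Feature Extraction's log ratio and with an offset of 10. At an unadjusted p under 0.05, limma called 1152 of the 3470 genes tested.

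The remaining lists were not shifted by camera. Where 5 or fewer members passed, they are named here after their values were seen. No member passed among 4 genes of the E. coli common pilus (median 0.41, camera adjusted p = 0.075), 20 of other chaperone-usher fimbriae (0.11, 0.075), 3 of antigen 43 and PGA (0.23, 0.18), 8 of cellulose synthesis (-0.23, 0.75), 10 of maltose uptake (0.17, 0.10), 8 of arginine synthesis (0.01, 0.53) and 8 of histidine synthesis (-0.10, 0.75), nor when adjusted over the list alone. Of 8 outer membrane porin genes, 4 fell both ways, namely ompX, ompC, ompW and ompA (median -0.78, adjusted p = 0.16). Of 23 cyclic di-GMP enzyme genes, dosC and dgcM fell both ways (-0.04, 0.89). Likewise rcsD and rcsB fell among 13 colanic acid and Rcs genes (-0.03, 0.75), and yccA and spy among 10 Cpx genes (-0.28, 0.75). Of 15 phosphate starvation genes, phoH, psiF and ugpB fell, and 4 genes fell when adjusted over the list alone (-0.57, 0.094). The high-affinity arabinose transporter genes araF (-2.34), araG (-2.34) and araH (-2.06) fell among 6 arabinose uptake genes, and 3 fell and 1 rose when adjusted over the list alone (median -1.22, adjusted p = 0.28). Of 22 anaerobic respiration and fermentation genes, 6 fell, led by pflB (-3.08), and aspA rose, against 7 and 1 adjusted over the list alone (-0.22, 0.38). Of 22 hydrogenase genes, hyaB, hyaC and hyaE fell and hybA and hybG rose, against 6 and 3 adjusted over the list alone (-0.17, 0.75). Of 17 TCA cycle genes, mdh, acnA and fumC fell and sdhB rose, against 3 and 2 adjusted over the list alone (0.08, 0.47). Of 9 cold shock genes, cspB and cspG rose and cspC and cspE fell, against 4 and 2 adjusted over the list alone (0.53, 0.14). Of 29 iron uptake genes, exbB and exbD fell (-0.06, 0.68). Of 23 nitrogen starvation genes, glnA rose and astB fell (-0.07, 0.75), and of 9 methionine synthesis genes metC rose (-0.04, 0.37). None of these iron, nitrogen and methionine genes passed when adjusted over the list alone. Relative to all genes, camera's direction was up for the iron, nitrogen, methionine, histidine and hydrogenase lists, whose medians were below 0, and up for the TCA cycle list, whose mean was -0.26, and the flagellar class 2 list, whose mean was -0.01. Of the tryptophanase genes, 2 were measured, too few for the list test, and tnaB passed (1.14 ± 0.41) while tnaA did not (-0.51 ± 0.42). As a control, 3 genes deleted in the parent strain had a median of 0.23 (camera adjusted p = 0.17). None of them passed over all genes, and araD (0.97 ± 0.58) rose when adjusted over the list alone. With processed signals 2 of the 3 rose, araD 2.84-fold (adjusted p = 0.0010) and rhaD 2.14-fold (adjusted p = 0.011), so the control fails there, and calls gained with processed signals have to be read with that in mind.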

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

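Of the tests here, those of stress genes far from the origin and of gene copies near it were chosen only after the pattern was seen.

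Probes without a K-12 locus tag entered no comparison, and some of them carried signal. Of 6457 such probes, 3431 (53.1%) were well above background in at least 1 channel on both arrays. Among these, 45 were at least 2-fold higher and 123 at least 2-fold lower in the FimZ channel on both arrays. Signal well above background does not show that a probe measures the gene it is named for. The same filter let through 3 genes deleted in the parent strain. The counts therefore do not name transcripts that changed.

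Transcripts of the RpoS and acid resistance lists were lower, with medians of -1.95 and -2.97, and rpoS itself had a log2 ratio of -1.41 ± 0.13 (n = 2, limma adjusted p = 0.018). Loess had already removed the average dye trend with brightness on each array, so random lists matched on brightness could weigh only what was left of it. Such a remainder is argued against, since the RpoS median lay at percentile 0 of 10000 of these lists. A dye effect that differs from probe to probe without regard to function would be random in such lists too. A different growth stage of the cultures stays open. Ribosomal protein genes, used most in growing cells, had a median log2 ratio of 0.18 (0.03 on replicate 1 and 0.41 on replicate 2). Of 52 tested, 1 rose with the main settings and none when adjusted over the list alone. With processed signals 13 rose and 2 fell, but the control of genes deleted in the parent strain fails there. The ribosome hibernation genes fell. Expression of FimZ, which the design names, stays open as well, and no growth data were analysed here to separate the explanations.

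SOS genes were higher, with a median log2 ratio of 0.98. What loess left of a dye trend with brightness is argued against by a percentile of 100 among lists matched on brightness. A place near the replication origin is argued against too, since the median lay at percentile 100 of 10000 lists matched on distance from the origin. FimZ expression, which the design names, and any other difference between the cultures stay open and were not separated here.

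Ratios followed the place of a gene on the chromosome, though not evenly. The median log2 ratio was -0.17 at 30% to 40% of the way from the replication origin and -0.03 at 40% to 50%. In MG1655 gene order, the median log2 ratio was 0.20 in the 10% of the way nearest to the replication origin, -0.06 at 40% to 60% of the way and -0.30 in the farthest 10% (Spearman's rho = -0.23 across 3470 genes, which are not independent; 164 of 3469 rotations of the gene order gave a correlation as strong in either direction, small shifts of the true order included). Genomic DNA in the cDNA stays open, since the offset shrinks the ratios of dim genes and so voids the main test (a difference between the nearest and farthest 20% of 0.95 in the brightest 25% of genes and 0.24 in the dimmest), and with processed signals the groups overlapped, at 0.92 (95% bootstrap interval 0.55 to 1.12), 0.62, 0.58 and 1.15 (0.64 to 1.64) from dimmest to brightest. A fall of stress genes lying far away stays open: the nearest 10% lay 0.26 above the middle, as much as in 173 of 3469 rotations, but the nearest 20% lay 0.15 above it, as much as in 1075 rotations, while 12.8% of the nearest 10% of genes rose against 2.7% and 2.6% at 40% to 50% and 50% to 60% of the way. More copies of origin-near genes in the FimZ-expressing culture stay a hypothesis. The correlation was below 0 on both chromosome arms and both arrays, and the weakest of the 4 was -0.20. Genomic DNA or a fall of far-lying stress genes could give the same signs, so this test cannot tell the explanations apart. Genes that rose were 12.8% of the nearest 10%, 2.9% at 10% to 20% of the way and 0.8% at 20% to 30%. Genes that fell were 4.1% in the nearest 10% and 19.6% in the farthest.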

How the results depend on the processing

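The direction of every named gene past the threshold and of each shifted list was the same under every alternative that gave a value, each array alone included, and fimZ passed in each tested one (log2 ratio 4.95 to 6.08). For the 12 highest and 12 lowest genes, the rule that chose them fixed the direction on each array alone, so that part says nothing about stability. Of the other comparisons with an alternative, 720 of named genes kept their side of the threshold, 33 lost the call and 101 gained one. For list medians these numbers were 226, 9 and 1. Outlier spots kept, the offset of 10 and the combined setting were chosen after seeing the data. Where the main settings called 116 higher and 401 lower genes, with 65 and 291 at least 2-fold apart on both arrays, processed signals called 564 and 967 (312 and 639 by size). Feature Extraction's log ratio called 645 and 928 (344 and 602), the deposited values also 645 and 928 (346 and 603), and processed signals with the filter on both channels 540 and 827 (256 and 493). An offset of 10 called 334 and 852 (124 and 458), scaling between the arrays 370 and 924, and no background subtraction 190 and 607. Median centring called 960 lower genes (27 and 512 by size). No filter on dim probes called 55 and 246, and a trended and robust prior 14 and 118; the cause was not tested. The main calls kept were 105 of the higher and 364 of the lower genes with processed signals. Each array alone gave 76 to 231 higher and 314 to 688 lower genes by size, since replicate 2 has the wider ratios. Adjusted p-values and list tests could not be had from 1 array, and a gene's value on 1 of 2 arrays always lies within 1 SD of their mean, so that comparison says nothing about stability. Shifted lists numbered 12 to 16, but 0 with an estimated correlation (lowest adjusted p = 0.81, none at an unadjusted p under 0.05) and 0 with fry (lowest adjusted p = 0.27, 3 at an unadjusted p under 0.05), against 14 with camera. The question differs, since fry sets a list against no change and camera sets it against the other genes. The estimated correlation and fry both rest on 1 residual degree of freedom. Without the replicate block, 91 and 379 genes passed. Low signal over background limits the dim genes: 1305 and 775 spots had a log ratio of exactly 0 from Feature Extraction.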

Other observations

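The gene groups in this paragraph were chosen after their values were seen, so their counts are descriptions. All 9 genes of the ATP synthase operon rose, with log2 ratios from 1.09 to 1.91 and a median of 1.45. The operon lies 0.3% of the way from the replication origin to the opposite point. Of 8 fatty acid degradation genes, 4 rose and none fell, with a median of 1.05. The thiolase gene fadA was at 2.46 ± 0.92 and fadB at 2.13 ± 0.78 (n = 2). Of 7 putrescine catabolism genes, 5 rose and none fell, with a median of 1.49, although they lie 89.1% of the way from the origin. All 4 propionate catabolism genes tested fell, with a median of -3.71 (-2.72 on replicate 1 and -4.71 on replicate 2).

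Some genes differed widely between the arrays, besides csgA and csgB. The porin gene ompF was at -0.55 on replicate 1 and 2.57 on replicate 2, and the cold shock gene cspA at 0.78 and 3.25. The gene lhgD of glutarate catabolism was at 2.48 and 0.23, and its neighbour glaH at 2.16 and -0.08. None of these passed the test.

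Prophage induction, which can follow the SOS response, was tested as a hypothesis. The 67 tested genes of the 4 prophages DLP12, e14, Rac and Qin had a median log2 ratio of 0.03, at percentile 91.44 of 10000 lists matched on brightness, short of the level set beforehand. Of these genes, 1 rose and 5 fell. DLP12, which lies next to fimZ, had a median of 0.19 over 14 genes, at percentile 97.71, and none of its genes passed.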
